A study of Mus musculus with 9 samples.

How the data were processed

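Germ cells were isolated from testes of wild-type ICR mice at postnatal day 35, per the labels' protocols, cross-linked, lysed and sonicated. Chromatin was then captured with biotinylated probes complementary to the long noncoding RNA Gm4665 or, as the control, with probes against LacZ, a bacterial gene that mice lack. DNA retrieved with each probe set and input DNA were sequenced as paired ends. The 9 samples form 3 groups of 3 replicates: Gm4665 probes, LacZ probes and input. Groups and replicate numbers were taken from the sample titles. Those titles and the column headers call the captured RNA LncRNA-20; that it is Gm4665 was taken from the labels' protocols for the same samples, and no label equates the names. The labels do not say whether replicates came from separate animals, so the spread between them may be partly technical.

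The values analysed here are those of 2 deposited peak lists, 1 for each probe set, made with MACS2 per the file names; version, settings and aligner are not given in the sources used here. Each row of a deposited list holds the position of a peak and, per the file headers, 1 linear fold enrichment over input for each of the 3 replicates. Every row held a fold for all 3 replicates. How the authors joined the replicates into 1 list is not given in the sources used here. Each row also holds a deposited pileup signal, the read coverage at the peak summit, whose replicate the headers do not name. In 47.6% of Gm4665 peaks and 52.9% of LacZ peaks, the replicate 1 fold divided by the pileup plus 1 was at its highest value within 0.0005 of that value as a fraction. For replicates 2 and 3 that share was 0.00258% of Gm4665 peaks and 0.0106% of LacZ peaks, so the pileup follows replicate 1 in both lists. The pileup was used only to describe the lists. The genome build was mm10, per the submitters' processing notes, and coordinates are 1-based. Input libraries entered only as the denominator of the authors' fold.

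Rows that repeated an interval, 649 in the Gm4665 list and 165 in the LacZ list, were joined with the highest fold of each replicate kept. Peaks on chromosomes 1 to 19, X and Y were analysed, which left out 116 Gm4665 and 25 LacZ intervals on other sequences. A mean fold is the mean over the 3 replicates with its SD. The 2 lists were normalized separately, so folds were ranked and described within a list and never tested across lists.

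Library read totals were not used here and depth is known only indirectly. Folds of a replicate fell on a grid: 48.2%, 54.9% and 52.6% of the deposited folds of Gm4665 replicates 1, 2 and 3 were whole multiples, within 0.01 of a step, of 0.341, 0.340 and 0.411. In the LacZ list 53.8%, 39.3% and 51.3% were multiples of 0.390, 0.455 and 0.577. If 1 step is 1 read over a constant background, the median peak rested on 33.4, 25 and 25 steps with the Gm4665 probes and on 59, 18.0 and 18.9 steps with the LacZ probes.

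Genes came from a RefSeq table of the same build, which gives start and end but no strand, exons or transcripts. Promoter windows had been planned before the data were examined; without strand they were replaced by gene-end windows, 2 kb either side of each annotated gene end, which cover the promoter and the 3' end alike. Of 49943 gene entries on these chromosomes, 340 that start below 3 Mb on chromosomes 1 to 19 or X were taken to carry scaffold coordinates and were left out; the lowest peak there started at 3000273, and the reading was not tested further. The 49603 genes used include 21779 protein-coding genes. Exons and introns were not separated.

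A Gm4665 peak was called specific when it overlapped no LacZ peak by 1 bp. Peak midpoints were assigned to gene ends, the rest of the gene, or intergenic sequence, in that order. Each share was set against 1000 random placements of the same peaks within their chromosome, and chromosome counts against 1000 draws over all chromosomes in proportion to their span. Random placement was not matched on GC content or mappability, since no genome sequence was used here. A value is called above or below random when under 2.5% of the draws were as high or as low. These are descriptions of the 2 lists, not tests across samples. The share of peaks at gene ends was compared between the lists with Fisher's exact test, two-sided, with 95% Wilson intervals, which cover counting error only.

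All 11 gene lists were fixed before the data were examined, and 1521 of 1521 members were found. Members with a specific peak at a gene end, or anywhere in the gene with 2 kb flanks, were counted and set against 10000 random lists of the same size matched on gene length in 20 bins. This made 22 comparisons for each peak list. Genes named in the text follow a rule fixed at the same time: Gm4665; the 10 genes with the strongest specific peaks at gene ends and the 5 strongest peaks elsewhere; up to 4 members of each list by fold; the 5 genes with the most peaks; and the 5 strongest LacZ genes at gene ends.

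The procedure was tested on simulated lists of 38000 peaks over 49603 genes. Of peaks moved to gene ends, planted as 5% of the list, 4.51% were recovered as excess over random; of an overlap planted at 3%, 3.02% was recovered; an X-to-autosome density of 0.4 was measured as 0.388. With nothing planted, 3.20% of random lists of 50 genes were called at gene ends. Alternatives covered a fold of at least 4 in all replicates, other definitions of shared and specific peaks, lists of equal size, other windows and gene sets, other random draws, and the replicates left out in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.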

Results

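The series asked where the long noncoding RNA Gm4665 contacts chromatin in male germ cells, with the regulatory regions of genes as the stated interest. Chromatin captured with Gm4665 probes and with LacZ control probes was sequenced beside input, with 3 replicates in each group. The Gm4665 list held 38711 peaks on the standard chromosomes, covering 25.5 Mb with a median width of 582 bp. The LacZ list held 9448 peaks covering 8.47 Mb with a median width of 844 bp. Median fold enrichment over input was 11.4, 8.50 and 10.3 in Gm4665 replicates 1, 2 and 3 (mean 10.1 ± 1.45, SD, n = 3). It was 23.0, 8.18 and 10.9 in the LacZ replicates (mean 14.0 ± 7.89, SD, n = 3). LacZ replicate 1 exceeded replicate 2 in 98.4% of LacZ peaks, with a median ratio of 2.62. Without LacZ replicate 1 the mean of the medians was 9.56. The lists were normalized separately, so these levels are not comparable as amounts of DNA. Across peaks, which are not independent replicates, Spearman's rho between replicates was 0.78 to 0.83 in the Gm4665 list and 0.66 to 0.73 in the LacZ list.

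The locus of the captured RNA was examined first, because probes that capture an RNA also retrieve the place where it is transcribed. Gm4665 (gene 100043812, a lncRNA) lies on chromosome 9 from 115178427 to 115186101 in mm10, inside the protein-coding gene Osbpl10, which encodes an oxysterol-binding protein family member. A single Gm4665 peak, from 115165775 to 115191874, covered the whole gene and extended 12652 bp before its start and 5773 bp past its end. Its fold was 128.5, 101.1 and 119.7 in the 3 replicates (mean 116 ± 14.0, SD, n = 3), the third highest in the list. No LacZ peak was listed within 10 kb of Gm4665. Probes complementary to the RNA also match the DNA of its gene, so this peak alone does not show retrieval through the RNA. Within 10 kb of Osbpl10, 3 other Gm4665 peaks had mean folds of 13.7, 10.8 and 6.46, and 1 LacZ peak had 13.0 ± 6.77 (SD, n = 3).

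One other region had a peak of this size. At Rai14, which encodes an actin-associated ankyrin-repeat protein, a Gm4665 peak ran from 10568392 to 10595320 on chromosome 15. It was 26929 bp wide, beside 26100 bp at Gm4665, and covered one end of Rai14 (10568971 to 10719267) and the adjoining part of the gene. Its mean fold was 129 ± 13.1 (SD, n = 3), the second highest in the list. These were the only 2 of 38711 Gm4665 peaks over 10 kb; the next widest measured 6436 bp. The LacZ peak nearest to the Rai14 interval lay 2758 bp away with a mean fold of 8.47 ± 5.35 (SD, n = 3), higher than 9.54% of LacZ peaks. A stronger LacZ peak lay farther inside Rai14, from 10636880 to 10638647, with 17.9 ± 11.0 (SD, n = 3).

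**Figure D1:**
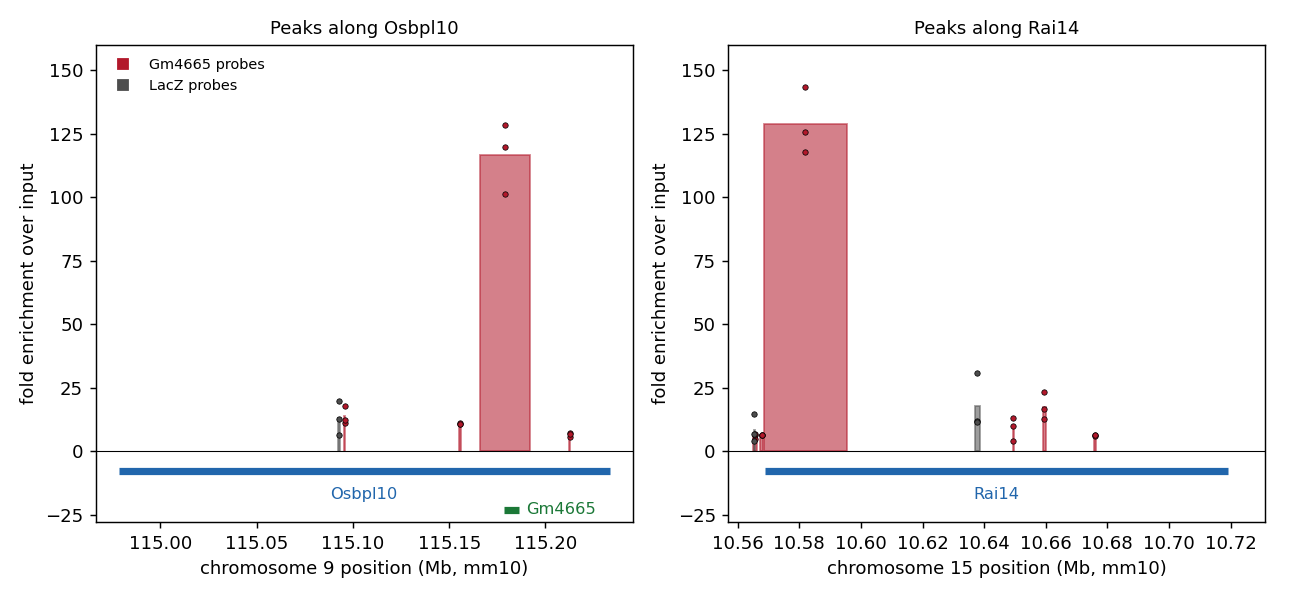
Fold enrichment over input (vertical axis, linear) of peaks along Osbpl10 with Gm4665 on chromosome 9 and along Rai14 on chromosome 15 (horizontal axis, position in Mb, mm10). Boxes span each peak at its mean fold, points are the 3 replicates drawn at the peak's centre, and bars below 0 mark the genes; the 2 wide boxes are the Gm4665-probe peaks of 26100 and 26929 bp, with mean folds of 116 and 129.

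Among specific peaks at gene ends, Rai14 and Gm4665 were followed by Gm19143, a pseudogene on chromosome 16, with a mean fold of 106 ± 16.0 (SD, n = 3). Sun5, which encodes a protein that attaches the sperm head to the tail, came next with 95.1 ± 11.2 (SD, n = 3). The Sun5 peak, from 153852086 to 153858521 on chromosome 2, was the widest after those at Rai14 and Gm4665. A peak on chromosome 11 shared by the lncRNA genes Gm34128 and Gm11729 had a mean fold of 71.7 ± 12.3 (SD, n = 3). Vcan, which encodes the matrix proteoglycan versican, had 70.9 ± 8.45, and Daw1, a dynein assembly gene, had 68.3 ± 8.51 (SD, n = 3 each). Crybb1, a lens crystallin gene, had folds of 45.4, 80.6 and 79.4 in the 3 replicates. H2-DMb1, an antigen-loading gene, had a mean fold of 68.3 ± 21.9 (SD, n = 3). Which genes made up the strongest 10 was not settled by 3 replicates: leaving out replicate 1, 2 or 3 kept 8, 7 or 7 of the 10.

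The strongest peak of the whole list by mean fold lay away from any gene end, inside Sema3e, which encodes a secreted guidance semaphorin. It ran from 14049692 to 14053724 on chromosome 5 with a mean fold of 143 ± 24.6 (SD, n = 3). Its rank rested on replicate 3: without that replicate, the mean was 130.5 at Sema3e, 134 at Rai14 and 136.6 at Insr. Peaks inside Stx11, a syntaxin gene, and Insr, the insulin receptor gene, had mean folds of 113 ± 5.23 and 113 ± 41.8 (SD, n = 3 each). The remaining 2 of the 5 strongest such peaks were intergenic. One began at 12175031 on chromosome 10 (116 ± 26.6, SD, n = 3) and one at 123752312 on chromosome 4 (110 ± 33.2, SD, n = 3).

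The LacZ control gave different leading regions. Its strongest gene-end peak lay at Abhd1 and Preb on chromosome 5, from 30954510 to 30960061, with a mean fold of 95.5 ± 54.4 (SD, n = 3). The pseudogene Gm13198 followed with 78.0 ± 39.3, then the nuclear receptor corepressor gene Nrip1 with 66.9 ± 36.2 and the lncRNA gene Gm40677 with 66.8 ± 25.4 (SD, n = 3 each). Fold was highest in replicate 1 at all 5 of these genes.

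The 2 lists shared few positions. Of the Gm4665 peaks, 344 (0.889%) overlapped a LacZ peak, against a mean of 0.586% when LacZ peaks were placed at random (central 95%, 0.511% to 0.664%), a ratio of 1.52. Among LacZ peaks, 345 of 9448 (3.65%) overlapped a Gm4665 peak. With the Gm4665 list reduced to its 9448 strongest peaks, the overlap was 1.11 times random and within the random range. The 38367 peaks without overlap are the specific peaks described from here on. Specific means only that the shorter LacZ list held no peak there. LacZ signal at these positions was not measured, so it may be present below that list's threshold.

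Gene ends were moderately over-represented in both lists. Of specific Gm4665 peaks, 13.0% had their midpoint within 2 kb of a gene end, against 11.5% at random (central 95%, 11.2% to 11.8%), a ratio of 1.12. Of LacZ peaks, 16.0% did, against 11.6% at random (10.9% to 12.2%), a ratio of 1.38. The rest of the gene held 43.9% of specific peaks and 46.9% of LacZ peaks, against 42.0% at random for each. Intergenic sequence held 43.1% and 37.1%, against 46.4% at random. The share at gene ends was lower among specific peaks (4970 of 38367, 95% Wilson interval 12.6% to 13.3%) than among LacZ peaks (1511 of 9448, 15.3% to 16.7%). The odds ratio was 0.782, with p = 3.2e-14 by Fisher's exact test, two-sided. That test compares 2 lists of peaks, not conditions, and random placement was not matched on mappability.

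**Figure D2:**
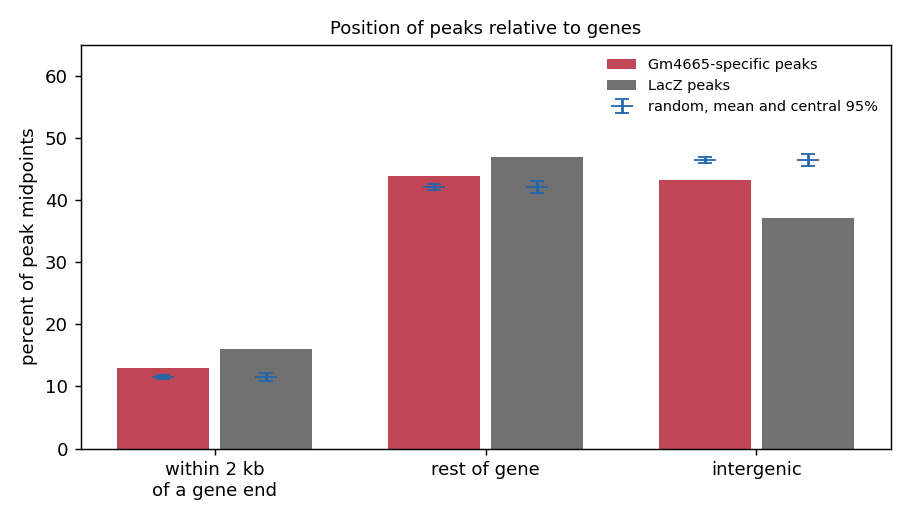
Percent of peak midpoints (vertical axis) within 2 kb of a gene end, in the rest of a gene, and between genes, for Gm4665-specific and LacZ peaks. Blue marks give the mean and central 95% of 1000 random placements; gene ends held 13.0% of specific and 16.0% of LacZ peaks.

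By gene, 6185 of 49603 genes had a specific Gm4665 peak at a gene end, 1.13 times the random mean of 5468 (central 95%, 5322 to 5609). LacZ peaks marked 2053 genes, 1.39 times their random mean of 1481. With all Gm4665 peaks, those overlapping LacZ peaks included, 6256 genes were marked and 318 of them also by LacZ peaks. Random gene sets matched on length shared 278 (central 95%, 249 to 309), and independent lists would share 259. With specific peaks, from which LacZ overlaps had been removed, 252 genes were shared, against 275 (246 to 305), within the random range. Genes with the most specific peaks were very long: Macrod2 held 33 peaks over 1998 kb, Cdh13 held 28 over 1185 kb, Magi2 held 27, Dlg2 held 25 and Lsamp held 23. At 10.5 to 23.6 peaks per Mb, these 5 genes lay on either side of the autosomal density of 15.5 per Mb.

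Peaks were sparse on the sex chromosomes. Specific Gm4665 peaks numbered 5.36 per Mb on X and 2.15 per Mb on Y, against 15.5 per Mb on the autosomes, which gives ratios of 0.345 and 0.138. LacZ peaks showed ratios of 0.241 on X and 0.230 on Y, against 3.83 per Mb on the autosomes. Chromosome 11 had the highest density in both lists (18.2 and 4.40 per Mb), 1.18 and 1.15 times the autosomal density. Random draws spanned X and Y too, so the sparse sex chromosomes lift most autosomes above them. Among the 9448 strongest Gm4665 peaks the X ratio was 0.183. Peaks that were listed on X had a median fold of 0.899 ± 0.0201 times that of autosomal peaks in the Gm4665 replicates and 0.929 ± 0.0619 times in the LacZ replicates (SD, n = 3 each). In LacZ replicate 1 the ratio was 1, against 0.889 and 0.897 in replicates 2 and 3. Folds fell on a grid, so medians moved in steps and these ratios are coarse.

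**Figure D3:**
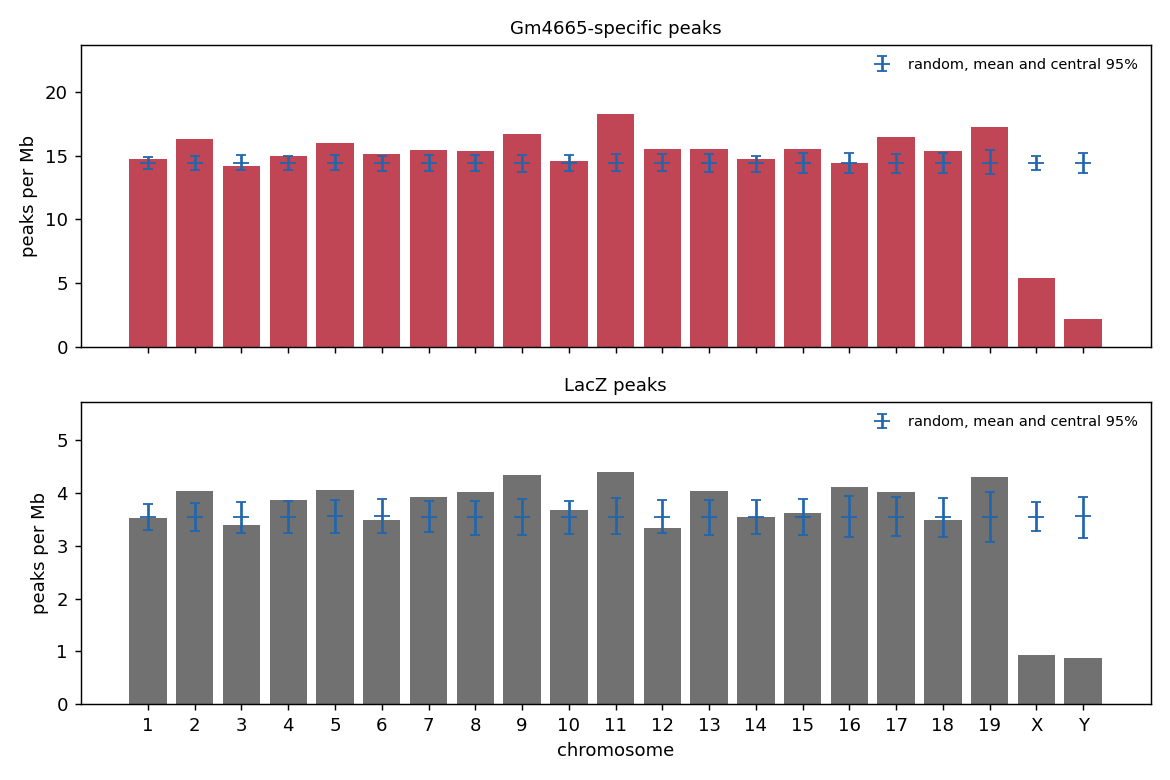
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) for Gm4665-specific and LacZ peaks, with the mean and central 95% of 1000 random draws over all chromosomes in blue. X and Y lie far below their random ranges in both lists, at 5.36 and 2.15 per Mb for specific peaks.

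Genes of spermiogenesis, the shaping of the sperm, had the most specific peaks at gene ends among the germ cell lists, without passing the random range. Of 62 members, 13 had one, against 8.51 in length-matched random lists (central 95%, 4 to 14). LacZ peaks lay at 1, against 2.80 at random (0 to 6). Beside Sun5, these included Rfx2, a transcription factor gene of spermiogenesis, with a mean fold of 24.6 ± 2.82. The acrosomal genes Spaca1 and Acrv1 had 20.1 ± 3.94 and 14.0 ± 0.358 (SD, n = 3 each). Over the gene with its flanks, 31 of 62 had a specific peak, against 24.6 at random (18 to 31), a ratio of 1.26; LacZ peaks lay in 14, against 10.3 (5 to 16), a ratio of 1.37.

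The meiotic prophase list gave the lowest count relative to random over whole genes for a list of the germ cell line. Over the gene with its flanks, 18 of 51 had a specific peak, against 24.8 at random (central 95%, 19 to 31), and 2.3% of random lists had as few. This was the only 1 of 22 comparisons outside the random range; at the 3.20% of random lists called in simulated data, 0.704 of 22 would be by chance. It came to lie within that range with a fold of at least 4 in all replicates (ratio 0.742), with lists of equal size (0.641) and on autosomes alone (0.734), and the ratio of 0.725 became 1.31 when random lists were not matched on gene length. At gene ends 3 members had a peak, against 7.59 at random: Stag3, which encodes a meiotic cohesin subunit (17.1 ± 3.01), Spata22 (7.63 ± 2.97) and Shoc1 (7.20 ± 1.35), both of meiotic recombination (SD, n = 3 each). LacZ peaks lay at the ends of 3 members, against 2.43 at random (0 to 6).

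Of 30 spermatogonial genes, 4 had a specific peak at a gene end, against 4.34 at random. They were the transcription factor genes Foxo1 (21.7 ± 0.899), Sall4 (17.2 ± 3.78), Sohlh1 (12.7 ± 4.28) and Pou5f1 (11.0 ± 3.30; SD, n = 3 each). Of 26 genes of the piRNA pathway, which silences transposons in germ cells, 3 had one, against 3.94 at random. These were Piwil1 (23.4 ± 2.84), Mov10l1 (12.3 ± 1.65) and Fkbp6 (8.81 ± 4.02; SD, n = 3 each). No LacZ peak was listed at the ends of piRNA pathway genes, against 1.25 at random.

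Lists for somatic cells of the testis were also within their random ranges. Sertoli cell markers had 2 of 25 members with a peak at a gene end, against 3.77 at random: the X-linked homeobox gene Rhox8 (19.8 ± 3.28) and Clu, which encodes clusterin (6.31 ± 0.680; SD, n = 3 each). Leydig, peritubular and macrophage markers had 5 of 20, against 2.85 at random. Among them, the steroid synthesis genes Hsd3b6 and Hsd17b3 had mean folds of 35.3 ± 4.36 and 21.0 ± 2.56. Pdgfra, a growth factor receptor gene, had 13.1 ± 1.71 and Vwf, an endothelial gene, had 10.6 ± 2.70 (SD, n = 3 each).

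Apoptosis genes had 7 of 35 members with a specific peak at a gene end, against 5.40 at random, and LacZ peaks lay at 4, against 1.68. Bik, a proapoptotic gene, had a mean fold of 30.4 ± 11.5, and Trp53, which encodes p53, had 28.8 ± 4.15. Bbc3, a target of p53, had 20.3 ± 4.75, and the survival gene Bcl2l1 had 12.7 ± 2.30 (SD, n = 3 each). The LacZ list also marked Bbc3 and Bcl2l1. Chromatin regulators had 9 of 50, against 7.59 at random. They included the histone methyltransferase gene Setdb1 (38.9 ± 2.22), the DNA methyltransferase gene Dnmt3a (38.2 ± 9.05), the deacetylase gene Hdac2 (31.4 ± 10.9) and the cohesin gene Rad21 (18.9 ± 5.16; SD, n = 3 each).

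Ribosomal protein genes had 9 of 80 members with a specific peak at a gene end, against 10.3 at random, led by Rpl7 (29.1 ± 6.49), Rpl37 (28.9 ± 5.34), Rpl8 (28.7 ± 2.96) and Rpl38 (27.8 ± 4.56; SD, n = 3 each). Olfactory receptor genes had 79 of 1109, against 89.1 at random, led by Olfr936 (38.8 ± 6.32), Olfr71 (35.8 ± 4.11), Olfr1106 (34.6 ± 8.67) and Olfr1097 (32.8 ± 5.12; SD, n = 3 each). LacZ peaks lay at 15 olfactory receptor genes, below the 25.9 at random (18 to 35). With 1 kb windows, olfactory receptors were below random in the Gm4665 list as well (44 against 57.1). Long neuronal genes had a specific peak in 33 of 33 members, against 30.3 at random (27 to 33), a range that ends at the full list, so no excess could be called. LacZ peaks lay in 29 of them, above the 18.8 at random (13 to 24). Among the 9448 strongest Gm4665 peaks, 31 of the 33 had a specific peak, above the 18.7 at random. Both counts may still follow gene length. The longest of the 20 length bins pools these genes with shorter ones, so matching on length was incomplete for them. At the ends of these long genes, Lsamp had a mean fold of 20.2 ± 3.06, Gpc6 11.9 ± 2.26, Nrg3 7.33 ± 2.82 and Dpp6 5.94 ± 2.17 (SD, n = 3 each).

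**Figure D4:**
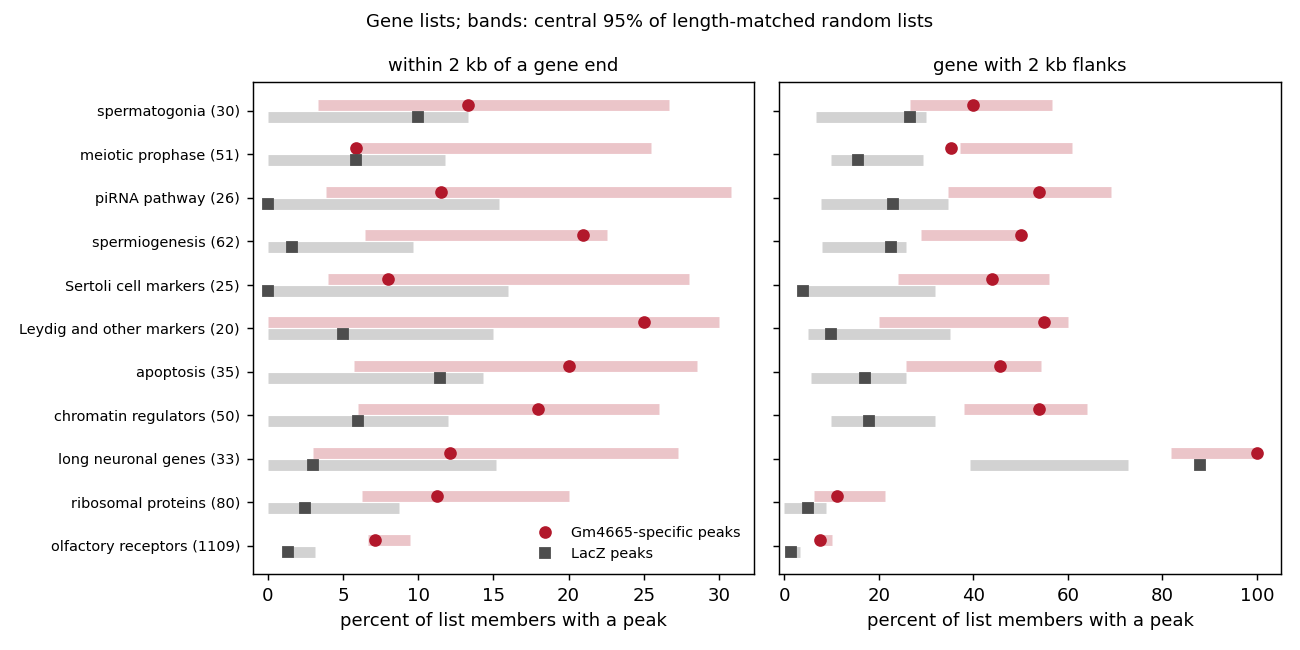
Percent of the members of each gene list (number of members in parentheses) with a peak at a gene end or in the gene with 2 kb flanks, for Gm4665-specific and LacZ peaks. Bands give the central 95% of 10000 length-matched random lists; for specific peaks only meiotic prophase over the gene, with 18 of 51 members, lies outside its band.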

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

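Circular shifts of peaks, autosomes alone, peaks under 5 kb and the genes marked by both lists were chosen after seeing the data. Gene-end shares stayed above random across all alternatives run (ratios of 1.11 to 1.13 for specific peaks and 1.36 to 1.51 for LacZ peaks). The odds ratio between lists stayed below 1 (0.709 to 0.795). The X-to-autosome ratio stayed low, at 0.183 to 0.350 for specific peaks and 0.241 to 0.242 for LacZ peaks. Only the fold filter could change that ratio for LacZ peaks, since the other settings run for it left their X and autosomal peaks unchanged. Overlap of the lists was 1.11 to 1.68 times random; it lay within the random range only with lists of equal size (1.11), where Gm4665 peaks were 9448 and genes with a specific gene-end peak 1709 by construction. Genes marked by both lists were 1.14 times random with all Gm4665 peaks and 0.916 times, within the random range, with specific peaks, from which LacZ overlaps had been removed. With 1 kb windows, 3730 genes had a specific and 1348 a LacZ gene-end peak; with protein-coding genes alone, 3054 and 1040, since fewer bases or genes were searched. The number of gene list comparisons outside the random range, 1 of 22, was 0 with a fold of at least 4 and 0 on autosomes, 3 with 1 kb windows and 9 with random lists not matched on gene length. The last of these follows gene length, and there the meiotic prophase ratio over the gene turned from 0.725 to 1.31; for the others the cause was not tested. Without each replicate in turn, the mean of the median folds was 9.39 to 10.8 in the Gm4665 list and 9.56 to 17.0 in the LacZ list. Peak positions could not be recomputed without a replicate, because each list holds 1 set of intervals for all 3. Ratios within a list were compared between probe sets by replicate. The median fold at gene ends over elsewhere differed by -0.00291 (Gm4665 minus LacZ), with exact permutation p = 1 without and with the replicate number as a block; that on X over autosomes differed by -0.0296, with p = 0.6 and, with the block, p = 0.75 (two-sided, n = 3). The smallest p that 3 against 3 allows is 0.1, or 0.25 with the block. Same-numbered replicates did not deviate together: over 344 shared positions, r was -0.0352, -0.0255 and -0.00884, and no Gm4665 replicate correlated best with its own number. Stricter q or p values, windows set by strand, GC-matched placement and the authors' own annotation were planned and not run, since the values they need were not used here. What depth limits was not measured, since library totals were not used here; 4.20% of Gm4665 peaks had a fold under 4 in at least 1 replicate.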

Other observations

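Comparisons of gene classes and the tests of the wide peak at Rai14, of the Gm4665 probe sequence on X and of gene ends were chosen only after those patterns had been seen. Classes of RNA genes differed in how often peaks lay at their ends. Small nuclear RNA genes, which encode splicing RNAs and exist in many near-identical copies, had a specific Gm4665 peak at 60 of 997 members, against 88.9 in length-matched random lists (central 95%, 74 to 104), and LacZ peaks at 17, against 36.6. Pseudogenes had 795 of 9854, against 862 (822 to 903), a ratio of 0.922. LacZ peaks lay at 275, against 298 (274 to 323), a similar ratio of 0.924 that was within the random range of that smaller list. Genes for lncRNAs had 1870 of 12639, against 1798 (1738 to 1860), while LacZ peaks lay at 565, within the random range (548 to 621). LacZ peaks lay at 1040 of 21779 protein-coding genes, against 1001 (964 to 1039), and at 36 of 1330 small nucleolar RNA genes, against 48.1 (37 to 59); specific peaks were within range for both classes. Transfer RNA genes were above random in the LacZ list alone, with 20 of 403, against 8.71 (4 to 14). These 20 genes may share fewer peaks. Specific Gm4665 peaks lay at 31, against 28.2 (19 to 38), and the difference between the lists was not tested. The widest LacZ peak, 16202 bp from 135040244 to 135056445 on X, lay inside the lncRNA gene 3632454L22Rik with a mean fold of 52.3 ± 15.6 (SD, n = 3), and the Gm4665 list had no peak within 10 kb of that gene.

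The peak at Rai14 was close to that at Gm4665 itself in width, unlike any other Gm4665 peak; in fold, narrow peaks such as those in Sema3e and Stx11 reached the same range. Unspecific pulldown at Rai14 would place a strong LacZ peak there; the strongest LacZ peak within 10 kb ranked above only 9.54% of that list, which argues against it. Sequence shared between the probes and the Rai14 interval may give such a peak by direct capture of DNA or of another RNA. This stays open, because neither probe nor genome sequence was used here; the LacZ list, whose probes match no mouse gene by design, also had 1 peak over 10 kb. Contact of Gm4665 RNA with Rai14 remains untested beside it, and a match of the probes to the interval would be the first thing to look for.

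Few peaks lay on X and Y with either probe set. A feature of the Gm4665 probes or RNA is argued against by the LacZ list, whose X-to-autosome ratio was 0.241. A single copy of X and Y in male cells may account for part of it. Halving the fold of autosomal peaks left a predicted share of 0.525 of specific peaks past the 1st percentile of each replicate, and the observed X-to-autosome ratio was 0.657 times that share; for LacZ peaks it was 0.494 times theirs. Both miss the tolerance of 1.5 times set beforehand, but that bound assumed a threshold of the peak caller: at the 5th percentile, tried after seeing the data, the observed ratio was 0.793 and 0.721 times the prediction and within it. Y fell further short, at 0.263 and 0.471 times the prediction at the 1st percentile and 0.318 and 0.687 times at the 5th, so specific peaks on Y were fewer than either assumption gave. Taken once per list rather than per replicate, the median fold on X was 0.904 and 0.955 times the autosomal one. That ratio was predicted as 0.786 and 0.697 at the 1st percentile and 0.927 and 0.841 at the 5th. Halving also assumes a background that does not change with copy number. Input DNA of male cells holds a single copy of X and Y too, so no drop is predicted where local input set the background. For that reason, and with the caller's threshold unknown, neither percentile decides the question. A single copy stays open, and low mappability was not tested.

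Gene ends held more Gm4665 peaks than random placement gave. Were this due to Gm4665 RNA at gene ends, specific peaks should exceed LacZ peaks there. The odds ratio was 0.782, so no excess over the LacZ list was seen. List size alone did not give the lower share: with the 9448 strongest Gm4665 peaks, 12.9% of specific peaks lay at gene ends and the odds ratio was 0.775. A share also falls when a list holds more scattered peaks, and the lists were called separately. The odds ratio therefore cannot decide whether Gm4665 RNA adds peaks at gene ends. An excess common to pulldowns is consistent with the LacZ list, whose gene-end share was 1.38 times random. Open chromatin at gene ends, or poor mappability between genes, could give either and was not tested.

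A further hypothesis was that contacts fall off with distance from the Gm4665 gene, written down before its test. Within 1 Mb of the gene, its own peak left out, 37 specific peaks were listed, against 33.6 in windows placed at random on chromosome 9 (central 95%, 18 to 49). No excess was detectable, and the counting interval of 26.1 to 51.0 leaves a modest one open. Within 5 Mb there were 185, against 170 (130 to 208), and within 100 kb there were 3, against 3.41 (0 to 8).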
